A study of Mus musculus with 8 samples.

How the data were processed

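RNA was measured in CD4+ CD25+ T cells sorted from the visceral adipose tissue and the spleen of wild-type (WT) and Id2-deficient (KO) C57BL/6 mice, with a minimum of 500 cells per sample per the labels. CD4 and CD25 together mark a gate rich in regulatory T cells (Tregs). Per the labels' protocols, cDNA was made with a SMARTer v4 ultra-low-input kit and libraries with a Nextera XT kit. The 4 groups held 2 libraries each, numbered 2 and 3, and these numbers are called experiments per the file headers. Nothing in the labels says whether the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be in part technical.

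The deposited table holds TPM, a unit of transcript share identified from the values: each of the 8 columns sums to 1000000, and low values of different genes in a library are not multiples of a common step. Reads were mapped to mm9 per the submitters' processing notes, and the aligner, the counting tool and the annotation are not given in the sources used here. The table lists 45232 gene names, of which 92.1% match symbols of GENCODE release M21, and 21784 were at 0 in every library. A spreadsheet had turned 27 gene names into dates, which were kept in counts but not named. The table gives no positions and its build differs from that of the annotation used here, so no coordinates are printed. TPM keeps no read depth, so the depth is unknown and no counting interval or detection floor is given. A value of 0 is described as listed at 0, although none of 26 housekeeping genes was at 0 in any library.

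Groups were compared with limma 3.58.1 in R 4.3.3, with a trend in the variance, on log2(TPM + 1). Genes with at least 1 TPM in at least 2 libraries were tested (13376 genes). All 8 libraries entered 1 fit with 4 groups and 4 residual degrees of freedom, because each group has only 2 libraries. The fit assumes the same spread of a gene in all groups. Across tested genes the SD of the log2 difference between the 2 libraries was 1.07 in WT and 1.49 in KO adipose tissue. In spleen it was 0.70 in WT and 0.84 in KO. A shared spread can therefore make p-values too large in spleen and too small in adipose tissue. The 5 contrasts were KO against WT in adipose tissue, KO against WT in spleen, adipose tissue against spleen in WT, the same in KO, and the genotype by tissue interaction. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a contrast, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes, and SE is limma's moderated standard error.

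Gene lists (28, of which 26 had enough tested members) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, beside camera with an estimated correlation and fry. With an estimated correlation no list passed in any of the 5 contrasts. Fry tests whether the genes of a list move 1 way on balance and does not compare them with other genes. Tests, alternatives, lists and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made after. By that rule Id2 is named in every comparison, with up to 8 genes of largest fold in each direction among those past the threshold, without overlap between groups (a condition not used for the interaction) and with a mean of at least 5 TPM in the higher group, or all genes of a direction where fewer than 5 pass. For each described list, the 4 members with the smallest p may be named. Clones, predicted genes, pseudogenes and antigen receptor segments are not named. Which lists to describe was chosen after their results were seen, and genes named outside the rule were chosen after their values were seen.

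Libraries with the same number deviated together: the correlation of the difference between experiments 3 and 2 across tested genes ranged from 0.128 to 0.382 over the 6 pairs of groups. The numbers were therefore taken as a possible pairing of the samples, from this check and the word experiment in the file headers. The check is weak, because the pairs of groups reuse the same differences. In each group experiment 3 also had more genes above 0 than experiment 2, and a shared difference in detection was not ruled out. The main fits held no block. Values with the replicate number as a block are given where they change the call of a list or of a gene that is named. They are also given where they move the number of genes called in a contrast, or that of called members of a described list, by over 1.5 times.

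The fits were tested on simulated data with 1 mean and 1 spread per gene, taken from all 8 libraries, and with genes drawn independently. Unequal spread between groups and correlation between genes were not simulated, so neither the fits nor camera were tested against them. For KO against WT in adipose tissue, 34 of 100 genes changed by 2 log2 units and 84 of 100 changed by 4 were recovered. None was called in the wrong direction. Of the 13376 genes tested, 13 unchanged ones were also called, beside the 34 and 84 recovered. These 13 were a larger share of the calls than the threshold on adjusted p-values aims to allow. For KO against WT in spleen with nothing changed, 0 genes were called. A glycolysis list shifted by 1 log2 unit in KO spleen was called at adjusted p = 4.57e-08, with 0 other lists called. Alternatives covered the block, each library left out, the 4 compared libraries alone, filters, library weights, quantile normalization, the trend, the pseudocount, the correlation used by camera and fry. Added after seeing the data were fits without both KO libraries of experiment 2, fits with hemoglobin and mitochondrial genes removed and the values rescaled, and list tests after quantile normalization. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.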

Results

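Transcript levels were measured in CD4+ CD25+ T cells sorted from visceral adipose tissue and spleen of WT and Id2-deficient mice, with 2 libraries in each of the 4 groups. The design asks how loss of Id2 and the tissue of residence bear on gene expression in these cells. Between 13184 genes (KO adipose 2) and 20684 genes (KO adipose 3) had a value above 0. The libraries of a group correlated across tested genes with r = 0.902 in WT adipose tissue, 0.812 in KO adipose tissue, 0.956 in WT spleen and 0.938 in KO spleen. Genes are not independent replicates. Over all tested genes the median log2 fold change was -0.27 for KO against WT in adipose tissue and -0.12 in spleen. It was 0.32 for adipose tissue against spleen in WT and 0.16 in KO. Quantile normalization moved these medians to -0.089, 0.0024, -0.0033 and -0.11. Changes of lists are therefore given by a test against the other genes.

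Id2, an inhibitor of E-protein transcription factors and the targeted gene, was at 2249 and 3679 TPM in WT adipose tissue and at 1499 and 1298 TPM in KO adipose tissue. In spleen it was at 274 and 346 TPM in WT and at 72.1 and 265 TPM in KO. The log2 fold change of KO against WT was -1.04 (SE 0.57, limma adjusted p = 0.751) in adipose tissue and -1.15 (SE 0.57, adjusted p = 1) in spleen. Neither difference passed the test, although each KO library lay below both WT libraries of its tissue. Without KO spleen 2 the spleen value was -0.22, and without KO spleen 3 it was -2.08. Without WT adipose 3 the adipose value was -0.69. Which part of the gene was removed is not given in the sources used here, and the table holds 1 value per gene. Id3, a related inhibitor, was at 25.1 and 22.3 TPM in WT and at 116 and 323 TPM in KO adipose tissue. It did not pass over all genes (2.98, SE 0.52, limma adjusted p = 0.0835). It did when adjusted over the list alone of 6 E and Id protein genes, and over all genes after quantile normalization (limma adjusted p = 0.0499). Without KO adipose 2 its log2 fold change was 3.72, but this rests on KO adipose 3 alone. In that library the macrophage list summed to 11219 TPM, against 15.8 TPM in KO adipose 2. A contribution of other cells to Id3 was not tested. Foxp3, the lineage factor of Tregs, was at 7.4 TPM in KO adipose 2 and 8.27 TPM in KO spleen 2. In the other 6 libraries it lay between 93.5 and 266 TPM.

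**Figure D1:**
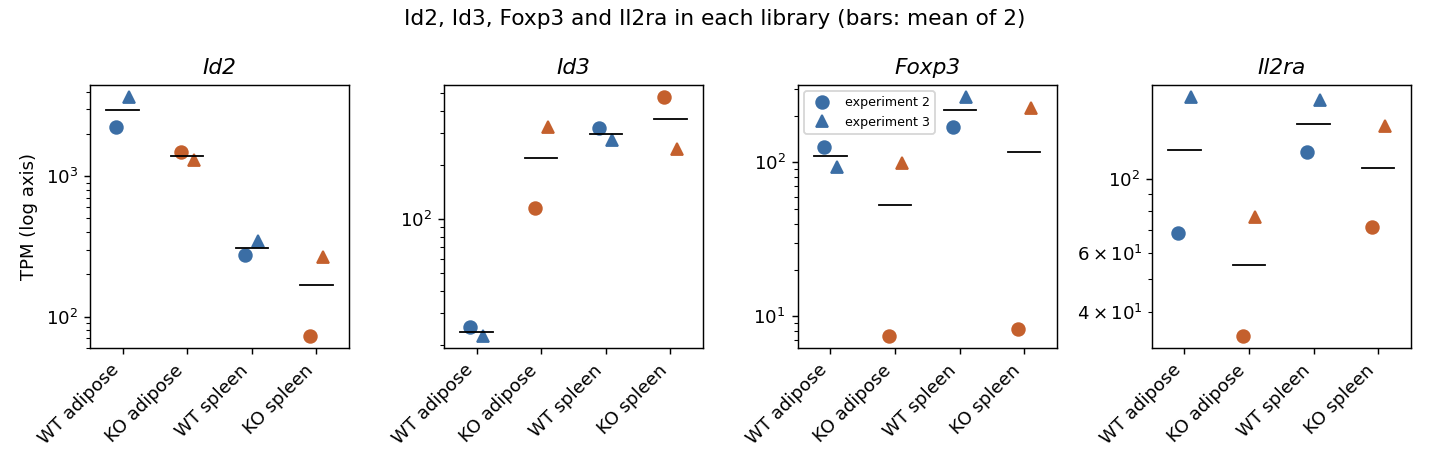
TPM (log axis) of Id2, Id3, Foxp3 and Il2ra in each library, with WT in blue, KO in orange, circles for experiment 2, triangles for experiment 3 and bars for the mean of 2 libraries. Id2 was higher in each adipose library than in each spleen library, and Foxp3 was at 7.4 and 8.27 TPM in the KO libraries of experiment 2.

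In adipose tissue, 38 genes differed between KO and WT, 37 higher and 1 lower in KO. Dcn, which encodes the matrix proteoglycan decorin, was at 404 and 2493 TPM in KO against 0.101 and 3.58 TPM in WT (log2 fold change 8.80, SE 0.95, adjusted p = 0.00934). Igfbp6, which encodes an insulin-like growth factor binding protein, was at 269 and 746 TPM against 0.038 and 0.839 TPM (8.34, SE 0.65, adjusted p = 0.00338). The complement gene C3 was at 108 and 310.2 TPM against 0.0164 and 0.212 TPM (7.37, SE 0.65, adjusted p = 0.00519). Rarres2, which encodes the attractant chemerin, was at 262 and 401 TPM against 0 and 3.51 TPM, and Efemp1, a matrix gene, at 333 and 128 TPM in KO. The complement inhibitor gene Serping1 (111 and 213 TPM in KO), Nkain4 (113 and 107 TPM) and the uroplakin gene Upk1b (113 and 106 TPM) were listed at 0 in both WT adipose libraries. All 37 higher genes were under 5 TPM in both WT adipose libraries, 17 of them listed at 0 in both, and 33 were under 1 TPM in all 4 spleen libraries. Rrm2, a subunit of ribonucleotide reductase, fell, at 9.3 and 8.76 TPM in KO against 158 and 98.9 TPM in WT (-3.65, SE 0.47, adjusted p = 0.0228). Igfbp6, Serping1, Nkain4 and Upk1b passed whichever library was left out, but not with the 4 adipose libraries alone (each adjusted p = 0.537), where limma called 0 genes, with 742 at an unadjusted p under 0.05. Dcn did not pass without WT adipose 2 (adjusted p = 0.058), KO spleen 2 (0.0621) or KO spleen 3 (0.0597). C3 and Efemp1 did not pass without WT adipose 3 (0.0527 and 0.0547), nor Rarres2 without KO spleen 2 (0.0544) or KO spleen 3 (0.055). Rrm2 did not pass without WT adipose 2 (0.164), WT adipose 3 (0.118), KO adipose 3 (0.108), WT spleen 2 (0.0866) or WT spleen 3 (0.0863). Dcn, Rarres2 and Rrm2 lost their calls without a filter on low values (0.0587 to 0.0801), Dcn, Efemp1 and Rarres2 with a pseudocount of 0.1 (0.0716 to 0.138), and Rarres2 without both KO libraries of experiment 2 (0.0644). The number of genes called was 343 without KO adipose 2, 66 without KO adipose 3, 14 without WT adipose 2 and 6 without WT adipose 3. It was 18 without WT spleen 2, 15 without WT spleen 3 and 14 without KO spleen 2 or KO spleen 3. Without both KO libraries of experiment 2 it was 162. It was 43 with the replicate block, 41 higher and 2 lower, which were Rrm2 and an antigen receptor segment.

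In the fibroblast and mesothelium list, all 8 tested members had positive fold changes in KO against WT adipose tissue (median 4.98, camera adjusted p = 1.9e-22, adjusted p = 0.46 with an estimated correlation). Of these, Dcn, Igfbp6, Msln and Upk3b passed over all genes, and 8 passed adjusted over the list alone. Msln and Upk3b did not pass without any 1 library other than KO adipose 2 or KO adipose 3 (adjusted p = 0.0664 to 0.193), nor without a filter on low values, with a filter at 5 TPM or with a pseudocount of 0.1 (0.0702 to 0.134), and Msln did not with a pseudocount of 5 (0.102). Other marker lists were called as higher as well. For macrophages and monocytes 11 of 11 members were positive (median 4.45, camera adjusted p = 3.17e-08, adjusted p = 0.771 with an estimated correlation), and for erythroid cells 7 of 7 (median 5.93, camera adjusted p = 2.63e-07, adjusted p = 0.771 with an estimated correlation). Over all genes 0 members of either list passed, and adjusted over the list alone 0 and 5 did. The macrophage call ended without KO adipose 3 (adjusted p = 0.126), where the macrophage gene Lyz2 was at 4982 TPM against at most 4.05 TPM in the other 3 adipose libraries. The dendritic cell (median 2.77, camera adjusted p = 0.0118, adjusted p = 0.771 with an estimated correlation), endothelium (median 1.41, camera adjusted p = 0.00898, adjusted p = 0.836 with an estimated correlation) and adipocyte lists (median 1.74, camera adjusted p = 0.0401, adjusted p = 0.836 with an estimated correlation) were also called. Without KO adipose 3 these 3 lists had adjusted p = 0.75, 0.711 and 0.75, and without WT adipose 2 they had 0.0532, 0.35 and 0.836. The adipocyte call also ended without KO spleen 2 or KO spleen 3 (both 0.0573) and after quantile normalization (0.0544), or with hemoglobin and mitochondrial genes removed (0.0792). All 11 T cell core genes had negative fold changes in KO against WT adipose tissue, with 0 past the test (median -0.67, camera adjusted p = 0.137, adjusted p = 0.836 with an estimated correlation). This list was called as lower without KO adipose 2 (adjusted p = 0.00129) and without both KO libraries of experiment 2 (0.0018).

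**Figure D2:**
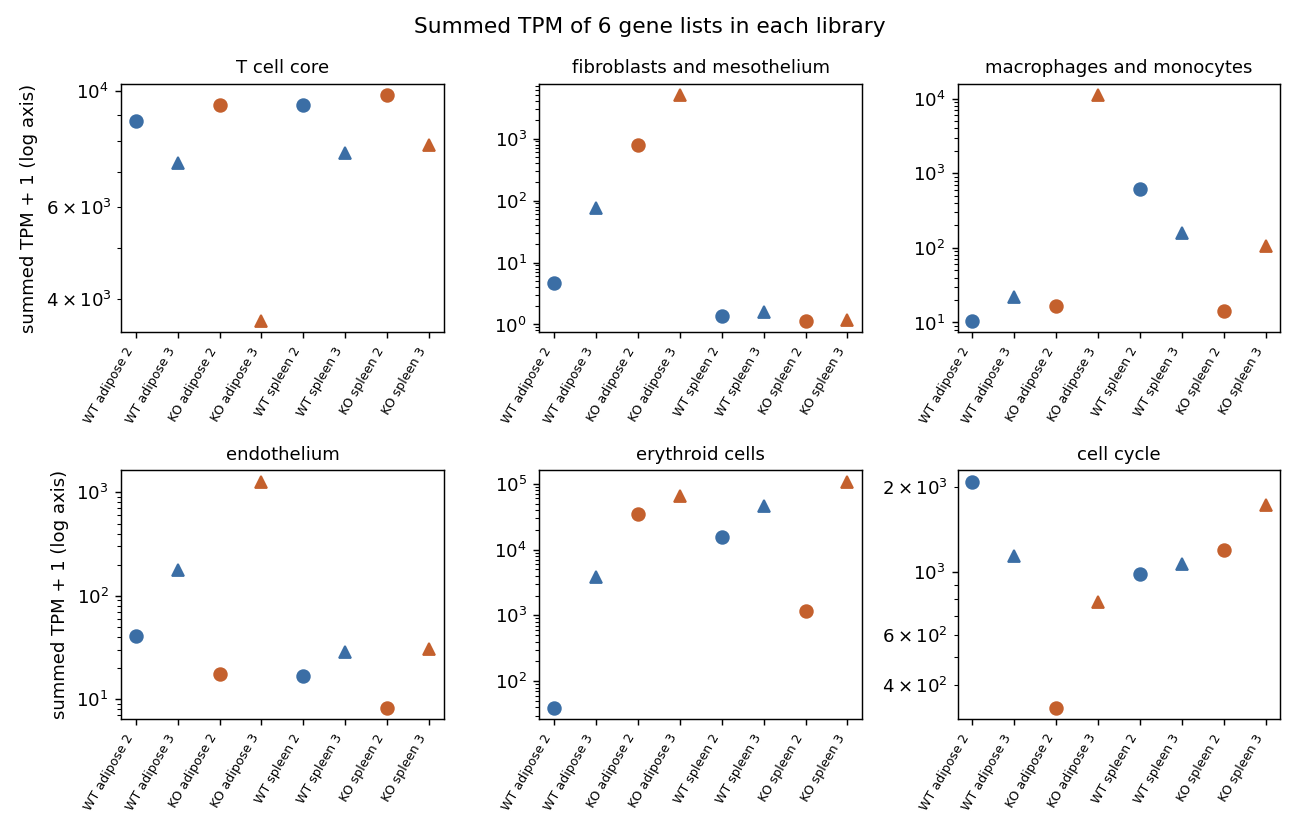
Summed TPM + 1 (log axis) of 6 gene lists in each library, with WT in blue, KO in orange, circles for experiment 2 and triangles for experiment 3. The fibroblast and mesothelium list summed to 789 and 5051 TPM in KO adipose tissue against 3.71 and 76.2 TPM in WT, and the macrophage list reached 11219 TPM in KO adipose 3.

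All 26 cell cycle genes had negative fold changes in KO against WT adipose tissue (median -1.69, camera adjusted p = 3.17e-08, adjusted p = 0.771 with an estimated correlation). In experiment 2 the median log2 level of the list was 5.602 in WT and 2.139 in KO adipose tissue. In experiment 3 it was 4.616 in WT and 4.441 in KO adipose tissue. The size of the fall therefore rests largely on KO adipose 2. Rrm2 passed over all genes and 3 members adjusted over the list alone. The thymidylate synthase gene Tyms was at 8.04 and 9.91 TPM in KO against 36.4 and 26.8 TPM in WT, and Stmn1, a microtubule regulator, at 31.3 and 149 TPM against 397 and 366 TPM. Stmn1 passed only without KO adipose 3 (adjusted p = 0.04). In the same libraries the fibroblast and mesothelium list was called as higher, with the values given above. The T cell core list, which did not pass, summed to 9372 and 3621 TPM in KO adipose tissue against 8743 and 7258 TPM in WT. The adipose Treg signature did not pass (6 of 22 positive, median -0.34, camera adjusted p = 0.728, adjusted p = 0.946 with an estimated correlation), with Prdm1, which encodes the repressor Blimp-1, at 2.62 and 6.19 TPM against 22.6 and 15.2 TPM. Treg identity did not pass either (median -0.28, camera adjusted p = 0.888, adjusted p = 0.946 with an estimated correlation), and its median was negative while its test against the other genes pointed up. Glycolysis (0 of 15 positive, median -0.55, camera adjusted p = 0.113, adjusted p = 0.836 with an estimated correlation) did not pass, but was called as lower without KO adipose 2 (adjusted p = 0.0446) and without both KO libraries of experiment 2 (0.0389). Neither did pro-survival (2 of 14 positive, median -0.49, camera adjusted p = 0.232, adjusted p = 0.836 with an estimated correlation) or pro-apoptotic genes (4 of 15 positive, median -0.59, camera adjusted p = 0.524, adjusted p = 0.836 with an estimated correlation). Bcl2, which protects from cell death, was at 35.6 and 29.5 TPM in KO against 87.6 and 89.95 TPM in WT and passed adjusted over the list alone but not over all genes (-1.43, SE 0.33, adjusted p = 0.22).

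In spleen, no gene passed the test of KO against WT: limma called 0 genes, with 64 at an unadjusted p under 0.05 where 668.8 would be expected by chance. The spread was shared with the adipose libraries, which varied more, and this can hide differences in spleen. The count of 0 therefore does not show that the genotypes were alike. Limma again called 0 with the replicate block, with 130 at an unadjusted p under 0.05, and with the 4 spleen libraries alone 0, with 268. The cell cycle list was called as higher, with 25 of 26 members positive (median 0.43, camera adjusted p = 2.52e-06). Tyms was at 37.2 and 38.5 TPM in KO against 19.5 and 20.1 TPM in WT. Glycolysis (12 of 15 positive, median 0.12, adjusted p = 0.0259) and follicular helper genes (7 of 10 positive, median 0.23, adjusted p = 0.0351) were called as higher. The adipose Treg signature (19 of 22 negative, median -0.56, adjusted p = 0.0351), naive and lymphoid homing genes (11 of 14 negative, median -0.66, adjusted p = 0.0272) and macrophage genes (11 of 11 negative, median -1.29, adjusted p = 0.0259) were called as lower. The homing regulator gene Klf2 was at 33.7 and 37.6 TPM in KO against 93.2 and 75.2 TPM in WT. Each of the 6 lists had adjusted p = 0.94 with an estimated correlation, and 0 of their members passed over all genes or adjusted over the list alone. With the replicate block the homing list was not called (adjusted p = 0.0635), and the immediate early list was called as lower (0.0389, against 0.0972). The latter was also called without KO spleen 2 (0.00637), without both KO libraries of experiment 2 (0.0044) and after quantile normalization (0.0358).

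The cell cycle call in spleen ended without KO spleen 3 (adjusted p = 0.179). The glycolysis call ended without WT spleen 2 (0.484), without KO spleen 3 (0.395) and after quantile normalization (0.161). The follicular helper call ended without WT spleen 2 (0.268), WT spleen 3 (0.151), KO spleen 2 (0.554) or KO spleen 3 (0.174), with a filter at 5 TPM (0.259) and after quantile normalization (0.105). The adipose Treg signature call ended without KO adipose 2 or KO adipose 3 (both 0.0711), WT spleen 2 (0.424) or KO spleen 2 (0.89). The homing and macrophage calls ended without WT spleen 2 (both 0.513), without KO spleen 2 (0.0539 and 0.0663) and without KO spleen 3 (both 0.347). Without both KO libraries of experiment 2 the follicular helper (0.153), adipose Treg (0.695) and homing calls (0.0584) ended.

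In WT cells, 22 genes differed between adipose tissue and spleen, 18 higher and 4 lower in adipose tissue. Immediate early genes, which are induced within minutes of stimulation, were among the highest folds. Any difference in how the tissues were handled before the sort cannot be told apart from the tissue itself, in WT or in KO. Its part in the level of these genes was not tested. Fos was at 1475 and 3107 TPM in adipose tissue against 6.11 and 15.2 TPM in spleen (log2 fold change 7.64, SE 0.57, adjusted p = 0.00482). Fosb was at 31.1 and 107 TPM against 0.448 and 0.463 TPM (5.34, SE 0.67, adjusted p = 0.0346). The phosphatase gene Dusp1 was at 1864 and 1882 TPM against 46.6 and 71.3 TPM (SE 0.35, adjusted p = 0.00482). The chemokine receptor gene Cxcr6 was at 1658 and 3398 TPM against 34.5 and 38.8 TPM (5.98, SE 0.52, adjusted p = 0.00966). The ubiquitin ligase gene Rnf128 was at 106 and 395 TPM against 1.35 and 1.83 TPM. Anxa1, which encodes annexin A1, was at 271 and 681 TPM against 13.4 and 11.3 TPM, and Tmem176b at 658 and 1171 TPM against 31.2 and 33.6 TPM. AA467197 (138 and 23.7 TPM) was listed at 0 in both WT spleen libraries. Lower in adipose tissue were the cytokine gene Il18 (0.474 and 0 TPM against 22.6 and 27.2 TPM) and the epoxide hydrolase gene Ephx1 (43.1 and 31.8 TPM against 230.4 and 177 TPM). Id2 did not pass in WT (3.22, SE 0.57, adjusted p = 0.0835). Each gene named here as higher or lower lost its call without WT spleen 2 (adjusted p = 0.0754 to 0.494). All but Dusp1 lost it without KO adipose 2 (0.0696 to 0.104) or KO adipose 3 (0.0719 to 0.104), and all but Fos and Dusp1 without WT spleen 3 (0.106 to 0.318). All but Fos, Dusp1 and AA467197 lost it without WT adipose 3 (0.0538 to 0.304). AA467197 and Ephx1 lost it without WT adipose 2 (0.0532 to 0.0602). These genes, Fosb and Il18 lost it without KO spleen 2 (0.0566 to 0.0819) or KO spleen 3 (0.054 to 0.0798). Fosb, AA467197, Tmem176b and Ephx1 lost it without the trend (0.0702 to 0.0995), Fosb, AA467197 and Il18 with a pseudocount of 5 (0.063 to 0.0894), and Fosb and AA467197 after quantile normalization (0.0549 to 0.0659). Id2 passed without KO spleen 2 (0.0495) or KO spleen 3 (0.0433) and with library quality weights (0.0195). With the replicate block 78 genes differed between the tissues in WT, 67 higher and 11 lower. The count was 39 without WT adipose 2, 3 without WT adipose 3, 0 without WT spleen 2 (by limma, with 655 at an unadjusted p under 0.05) and 2 without WT spleen 3. It was 1 without KO adipose 2 or KO adipose 3, which are not compared but enter the estimate of the spread. With the 4 WT libraries alone limma called 0 genes, with 2543 at an unadjusted p under 0.05, and without a filter on low values 0, with 1961. Without both KO libraries of experiment 2 it called 0, with 2549, and Fos, Cxcr6 and Dusp1 each had adjusted p = 0.112.

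In the immediate early list 22 of 24 members were positive in WT adipose tissue, 6 of them past the test over all genes (12 with the replicate block) and 17 adjusted over the list alone (median 2.92, camera adjusted p = 8.49e-12, adjusted p = 0.252 with an estimated correlation). The adipose Treg signature had 19 of 22 members positive (median 2.25, camera adjusted p = 0.000256, adjusted p = 0.42 with an estimated correlation). Cxcr6 passed over all genes (2 members with the block, where Ccr2 had adjusted p = 0.0369), and 10 higher and 1 lower adjusted over the list alone. Ccr2 also passed without KO spleen 2 (0.0322) or KO spleen 3 (0.0334), with a filter at 5 TPM (0.0429), with library quality weights (0.0167) and with a pseudocount of 5 (0.0325). Treg identity had 18 of 20 members negative, 0 past the test over all genes and 5 adjusted over the list alone (median -1.01, camera adjusted p = 3.39e-08, adjusted p = 0.252 with an estimated correlation). Its activation receptor gene Tnfrsf9 was at 22.7 and 69.3 TPM against 321 and 264 TPM, and passed with library quality weights (adjusted p = 0.0214). Glycolysis had 15 of 15 members positive, 0 past the test over all genes and 3 adjusted over the list alone (median 1.39, camera adjusted p = 0.00012, adjusted p = 0.362 with an estimated correlation). Lipid metabolism had 21 of 26 positive, 0 and 6 by the same counts (median 1.10, camera adjusted p = 0.00817, adjusted p = 0.72 with an estimated correlation), and was not called without WT adipose 3 (adjusted p = 0.0614). Pparg, a regulator of lipid genes, was at 25.6 and 154 TPM in adipose tissue against 4.26 and 2.7 TPM in spleen. Follicular helper genes had 8 of 10 negative, with 0 members past either test (median -1.10, camera adjusted p = 0.000236, adjusted p = 0.252 with an estimated correlation). Beside these, macrophage genes (10 of 11 negative, median -3.29, camera adjusted p = 0.000236, adjusted p = 0.624 with an estimated correlation) and erythroid genes (7 of 7 negative, median -4.77, camera adjusted p = 9.04e-06, adjusted p = 0.42 with an estimated correlation) were called as lower in WT adipose tissue. Over all genes or over the list alone 0 members of either list passed. Adipocyte (6 of 7 positive, median 1.97, camera adjusted p = 0.268) and endothelium genes (8 of 8 positive, median 1.42, camera adjusted p = 0.517) were not called. The adipocyte list summed to 5.41 and 185 TPM in WT adipose 2 and 3, and the lipid metabolism list to 737 and 3632 TPM.

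In KO cells, 144 genes differed between the tissues, 124 higher and 20 lower in adipose tissue. Among the largest folds were those of Dcn (9.95, SE 0.95, adjusted p = 0.0042), Igfbp6, Rarres2, Efemp1, Serping1, C3 (108 and 310.2 TPM against 0.164 and 0.782 TPM) and Nkain4. Fos was at 1779 and 1525 TPM in adipose tissue against 6.48 and 2.21 TPM in spleen (8.39, SE 0.57, adjusted p = 0.00177). Cxcr6 was at 1442 and 1063 TPM against 31.2 and 85.9 TPM (4.55, SE 0.52, adjusted p = 0.0109). The type 2 cytokine gene Il5 was at 80.2 and 129 TPM against 0 and 0.192 TPM (6.55, SE 0.97, adjusted p = 0.0267). Lower in adipose tissue were Pdzk1ip1 (2.7 and 1.16 TPM against 142 and 28.1 TPM), the receptor gene Cd160 (0 and 1.07 TPM against 35.6 and 15.2 TPM) and the interferon-induced gene Gbp10 (0.103 and 0.53 TPM against 9.12 and 15.9 TPM). Prss2, Noxa1 and Lrr1 were listed at 0 in both KO adipose libraries. Oip5 (0 and 0.171 TPM against 15.8 and 15.4 TPM) and Ska1 (0 and 0.0285 TPM against 6.74 and 11.1 TPM), which act in chromosome segregation, were lower as well. Id2 passed (3.32, SE 0.57, adjusted p = 0.0424) with all 8 libraries, but not without any 1 of 7 of them, with an adjusted p between 0.0635 (without WT adipose 3) and 0.218 (without KO spleen 2). Of the fits that left out 1 library, it still passed in that without KO spleen 3. It did not pass with the 4 KO libraries alone, without a filter on low values, with library quality weights, without the trend or with a pseudocount of 0.1 or 5 (0.0583 to 0.199). Fos passed whichever library was left out. Without KO spleen 2 each other gene named here as different lost its call, with adjusted p = 0.0543 to 0.0811 for Dcn, Igfbp6, Rarres2, Efemp1, Serping1, C3, Nkain4 and Cxcr6. Dcn and Rarres2 also lost it without KO spleen 3 (0.0504 to 0.058), and Cxcr6 without KO adipose 3 (0.0566). Il5 and the genes lower in adipose tissue, with Lgals3, Ccr2, Tnfrsf9 and Rrm2 of the lists, lost it without KO spleen 2 (0.0811 to 0.436), KO adipose 3 (0.0684 to 0.17), WT spleen 2 (0.06 to 0.125) or WT spleen 3 (0.0617 to 0.126). All of these but Ccr2 lost it without KO spleen 3 (0.0573 to 0.149), and all but Il5, Noxa1 and Tnfrsf9 without WT adipose 2 (0.0502 to 0.0639). Ccr2, Gbp10, Lgals3, Pdzk1ip1, Prss2, Rrm2 and Ska1 lost it without WT adipose 3 (0.0534 to 0.0635), and Ccr2, Cd160, Prss2, Rrm2 and Tnfrsf9 without KO adipose 2 (0.0562 to 0.0705). Il5, the lower genes, the 4 list genes and Cxcr6 lost it without a filter on low values (0.0626 to 0.195), all of these but Il5 with the 4 KO libraries alone (0.0837 to 0.262) and all but Cxcr6 with library quality weights (0.0779 to 0.141). With a pseudocount of 5 Il5, Rrm2 and each lower gene but Noxa1 lost it (0.0676 to 0.114), and with a pseudocount of 0.1 Ccr2, Cd160, Pdzk1ip1, Prss2 and Rrm2 (0.0522 to 0.128). Ccr2, Lgals3, Pdzk1ip1, Prss2, Rrm2 and Tnfrsf9 lost it without the trend (0.0512 to 0.0645), and Prss2 and Ska1 with a filter at 5 TPM (0.0502 to 0.0527).

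In KO, 22 of 24 immediate early genes were positive in adipose tissue, 9 past the test over all genes and 14 adjusted over the list alone (median 2.62, camera adjusted p = 4.48e-12, adjusted p = 0.316 with an estimated correlation). The adipose Treg signature had 18 of 22 members positive (median 2.96, camera adjusted p = 1.08e-05, adjusted p = 0.431 with an estimated correlation). Cxcr6, Lgals3 and Ccr2 passed over all genes, and 12 higher and 2 lower adjusted over the list alone. Treg identity had 17 of 20 negative, with Tnfrsf9 past the test (3 members with the replicate block, where Izumo1r and Tnfrsf4 had adjusted p = 0.0463 and 0.0489, and without KO adipose 2 0.0485 and 0.0483) and 4 adjusted over the list alone (median -1.16, camera adjusted p = 7.31e-06, adjusted p = 0.316 with an estimated correlation). All 26 cell cycle genes were negative, with Rrm2 past the test (2 members with the block, where Tyms had adjusted p = 0.0463, and 0.0244 after quantile normalization) and 3 adjusted over the list alone (median -1.60, camera adjusted p = 3.35e-11, adjusted p = 0.472 with an estimated correlation). All 8 fibroblast and mesothelium genes were positive, 5 past the test and 8 adjusted over the list alone (median 6.23, camera adjusted p = 1.57e-13, adjusted p = 0.316 with an estimated correlation). Lipid metabolism had 23 of 26 positive, 0 past the test by limma (1 with the block, Pparg at adjusted p = 0.0478) and 1 adjusted over the list alone (median 0.95, camera adjusted p = 0.0049, adjusted p = 0.642 with an estimated correlation), and was not called without KO adipose 3 (adjusted p = 0.484). The Th2 list had 7 of 7 positive, with Il5 past the test and 1 adjusted over the list alone (median 0.95, camera adjusted p = 0.0144, adjusted p = 0.55 with an estimated correlation). It was not called without KO adipose 2 (0.0548) or KO adipose 3 (0.147), or without both KO libraries of experiment 2 (0.0853). Beside these, macrophage (median 3.30, camera adjusted p = 0.0112, adjusted p = 0.673 with an estimated correlation), adipocyte (median 2.75, camera adjusted p = 0.0112, adjusted p = 0.642 with an estimated correlation) and endothelial genes (median 3.03, camera adjusted p = 0.0109, adjusted p = 0.642 with an estimated correlation) were called as higher in KO adipose tissue. Over all genes 0 of their members passed, and adjusted over the list alone 0, 2 and 1 did. These calls ended without KO adipose 3 (adjusted p = 0.472, 0.645 and 0.857) and without KO spleen 3 (0.0877, 0.163 and 0.169), and that of macrophages with a filter at 5 TPM (0.13).

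**Figure D3:**
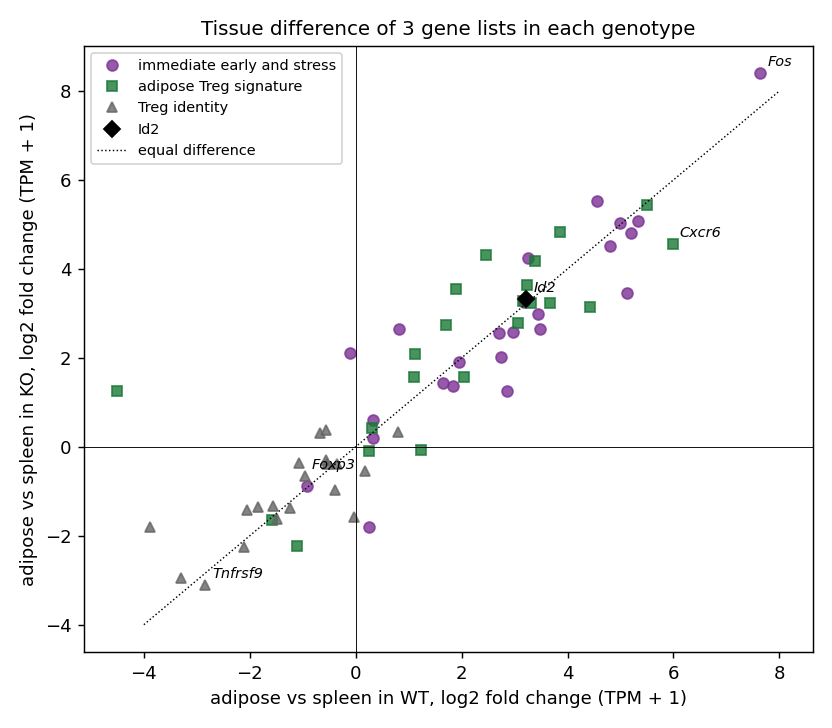
Log2 fold change on TPM + 1 of adipose tissue against spleen in WT (x axis) and KO (y axis), each point a gene of the immediate early, adipose Treg or Treg identity list, with Id2 as a diamond and the dotted line marking equal differences. Fos lay at 7.64 in WT and 8.39 in KO, and Id2 at 3.22 and 3.32.

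With the replicate block 236 genes differed between the tissues in KO, 190 higher and 46 lower, and after quantile normalization 173 were higher and 58 lower. The count was 663 without KO adipose 2, 83 without KO adipose 3, 1 without KO spleen 2 and 21 without KO spleen 3. It was 92 without WT adipose 2 and 25 without WT spleen 2 or WT spleen 3. With the 4 KO libraries alone it was 12. Without both KO libraries of experiment 2 limma called 0 genes, with 1627 at an unadjusted p under 0.05.

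The tissue differences of WT and KO share no libraries, though they share the estimate of the spread. Of the 18 genes higher in WT adipose tissue, 17 were among the 124 higher in KO, where independent lists would share 0.167. Of the 4 lower genes, 1 was among the 20 lower in KO, where independent lists would share 0.00598. In the other direction, 84 of the 124 genes higher in KO and 18 of the 20 lower ones had the same sign in WT. The share of all tested genes with the same sign is not given here. These counts therefore do not show that the KO calls recur in WT more than other genes do. Across the 13376 genes, which are not independent replicates, the fold changes correlated with r = 0.515 and rho = 0.551. The test of the interaction called 4 genes with all 8 libraries and no block: Igfbp6 (interaction 8.61, SE 0.91), Serping1 (7.58, SE 0.80), Nkain4 (6.80, SE 0.71) and Upk1b (6.78, SE 0.71), each with adjusted p = 0.0367. The interaction of Id2 was 0.10 (SE 0.81, adjusted p = 1). With the replicate block limma called 0 genes for the interaction, with 661 at an unadjusted p under 0.05, and the 4 genes had adjusted p = 0.0611 (Serping1) and 0.0506 (each other). The count was 177 without KO adipose 2, 8 without KO adipose 3 and 0 without any 1 of the other 6 libraries. Each of the 4 genes then had adjusted p = 0.161 without WT adipose 2, 0.209 without WT adipose 3, 0.457 without WT spleen 2, 0.377 without WT spleen 3, 0.382 without KO spleen 2 and 0.308 without KO spleen 3. In these fits 434, 430, 227, 334, 503 and 379 genes were at an unadjusted p under 0.05.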

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

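The tests on the fibroblast and mesothelium list, on the other Treg identity genes, on Foxp3 in experiment 3 and on KO adipose 3, with the comparisons of WT adipose 3, were chosen after the results were seen. With all 8 libraries and no block, a test of the interaction between genotype and tissue called Igfbp6 (8.61 log2 units), Serping1 (7.58), Nkain4 (6.80) and Upk1b (6.78), and camera called 6 lists. With the replicate block these genes did not pass (adjusted p = 0.0611 for Serping1 and 0.0506 for each other), nor without any 1 library other than KO adipose 2 or KO adipose 3 (0.161 to 0.457). The median interaction was 5.02 for fibroblasts and mesothelium, 5.32 for macrophages and monocytes, 2.97 for dendritic cells, 7.03 for erythroid cells, -2.21 for the cell cycle and -0.89 for glycolysis. With an estimated correlation the first of these had adjusted p = 0.485 and the others 0.642. The glycolysis call ended without KO adipose 3 (adjusted p = 0.218). The dendritic cell call ended without KO adipose 3 (0.54), WT spleen 2 (0.055) or KO spleen 3 (0.322). The erythroid call ended with hemoglobin and mitochondrial genes left out (0.0719), which removes hemoglobin members of the list itself and left 3 of its 7 tested members.

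Genes of the fibroblast and mesothelium list were higher in KO adipose tissue, and a candidate explanation is RNA of mesothelial cells, which a sort on CD4 and CD25 would be meant to remove. Of 12 further mesothelial genes, 3 of which reached 1 TPM in a spleen library, 11 were at 1 TPM or more in both KO adipose libraries and above both WT adipose libraries. That count rests on the loosest of 3 rules considered before the values were seen: also requiring under 1 TPM in WT adipose tissue left 7, and requiring over 5 TPM in KO and under 1 TPM in WT adipose tissue and spleen left 3, a count that by the terms set beforehand would have decided nothing. The highest value was that of Slpi in KO adipose 3 (601 TPM), but in KO adipose 2 Slpi (21.7 TPM) lay below Muc16 (33.7 TPM) and below its own level in WT spleen 2 (45.7 TPM). Greater depth of KO adipose 3 is argued against by 7 of the 8 tested fibroblast and mesothelium genes lying above both WT adipose libraries in KO adipose 2, the library with the fewest genes above 0, while an effect of the Id2 genotype on the tissue or the cells stays open and was not tested.

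Foxp3 was low in both KO libraries of experiment 2, with log2 ratios to the WT library of the same experiment of -3.92 in adipose tissue and -4.20 in spleen. The other 19 Treg identity genes did not fall as far as a set, with a median ratio of -0.50 (SD 0.81) over the values of both tissues. This cannot decide on fewer Tregs in the gate. The list holds Il2ra, the gene of the sort marker CD25, and activation receptor genes such as Tnfrsf9, which other CD25+ T cells may share. A general loss of transcripts of that length and level is argued against by matched genes, 185 in adipose tissue and 70 in spleen. Their median log2 ratios were -0.60 and -0.21, and their 5th percentiles -1.94 and -1.38. Foxp3 lay at percentile 0 in both, but it was singled out for its low values, so this rank is no independent evidence. A loss that struck single transcripts was not tested. Id2 genotype as the whole cause is argued against by experiment 3, where the lower of the ratios of Foxp3 was -0.23. Foxp3 was not alone, as Cd3e was also low in both KO libraries of experiment 2. In that experiment the median log2 level of the T cell core list was lower in KO than in WT. It was 7.68 against 8.39 in adipose tissue and 7.24 against 8.06 in spleen. The list sum was instead higher in KO, at 9372 against 8743 TPM and 9816 against 9399 TPM. No explanation tested was shown to account for the low Foxp3, and fewer Tregs in the gate stays open. A difference between the experiments in the mice or the Foxp3 locus was not tested.

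Macrophage and endothelial genes were high in KO adipose 3, where 12 of 12 macrophage and 8 of 8 endothelial genes had their highest value of the 8 libraries, with Lyz2 at 4982 TPM and C1qb at 2781 TPM. Such cells or their RNA may have been in this library despite the sort on CD4 and CD25: 9 of 11 T cell core genes were lower than in KO adipose 2 (median log2 ratio -0.82), and 11 of 11 lower than in WT adipose 3, with a list sum of 3621 TPM against 9372 TPM in KO adipose 2. Cd3e was higher in KO adipose 3 (393 TPM) than in KO adipose 2 (70.6 TPM), and the median log2 level of the list was too (8.30 against 7.68). This says little against a smaller share of T cells, because Cd3e was low in both KO libraries of experiment 2. Within experiment 3 KO adipose 3 had the lowest Cd3e, and the list median was 9.35 in WT adipose 3. In WT adipose tissue 7 of 11 T cell core genes were also lower in experiment 3, so the T cell share stays open. Greater depth is argued against by 9 of 12 macrophage genes at 100 TPM or more, where no other adipose library exceeded 16 TPM. An effect of genotype stays open and was not tested, and KO adipose 2 did not share these levels.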

How the results depend on the processing

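The fits without both KO libraries of experiment 2, the rescaled fits and the list tests after quantile normalization were chosen after seeing the data. Leaving out 1 of 2 libraries leaves a lone library that is assumed to vary like the others. Library quality weights came out equal for the 2 libraries of a group, at 0.554 in KO adipose tissue and 1.72 in WT spleen. They therefore weigh groups and not single libraries. The cause of the changes was not tested. Depth is unknown, so what it limits cannot be stated.

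For KO against WT in adipose tissue the 38 genes became 0 with the 4 compared libraries alone, 18 with a filter at 5 TPM, 72 with quantile normalization, 13 with a pseudocount of 0.1 and 162 without both KO libraries of experiment 2. With each library left out in turn they ranged from 6 to 343. In spleen limma called 0 genes in every fit, with 27 to 502 at an unadjusted p under 0.05. For adipose tissue against spleen in WT the 22 genes became 78 with the replicate block, 0 with 4 libraries, 0 without a filter, 59 with a filter at 5 TPM, 219 with library weights, 7 without the trend and 0 without both KO libraries of experiment 2. Left-out libraries gave 0 to 39. In KO the 144 genes became 236 with the block, 12 with 4 libraries, 63 without a filter, 48 with weights, 231 with quantile normalization, 70 and 89 with pseudocounts of 0.1 and 5 and 0 without both KO libraries of experiment 2. Left-out libraries gave 1 to 663. The 4 interaction genes became 0 with the block, without a filter, with a filter at 5 TPM, with a pseudocount of 0.1 and without both KO libraries of experiment 2 (661, 661, 246, 408 and 1083 at an unadjusted p under 0.05). They became 10 with weights, 10 with quantile normalization and 16 without the trend, and left-out libraries gave 0 to 177. With hemoglobin and mitochondrial genes left out each of these counts of genes stayed within 1.5 times, and the median of all genes for adipose tissue against spleen in WT moved from 0.32 to 0.18.

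Camera called 7, 6, 13, 13 and 6 lists in the 5 contrasts in this order. With an estimated correlation it called 0 in each, and fry called 0, 0, 0, 2 and 0. Without both KO libraries of experiment 2 the 7 became 11 and the last 6 became 12. Left-out libraries gave 5 to 12, 2 to 6, 9 to 16, 6 to 16 and 5 to 12. The replicate block changed no call of a list beyond those given for spleen and the endothelium list in the interaction (adjusted p = 0.0354, against 0.0605). The endothelium list was also called in the interaction without KO adipose 2 (3.13e-06) or WT adipose 3 (0.00103), without both KO libraries of experiment 2 (7.29e-06) and after quantile normalization (0.0347). Id2 ranged from -1.40 to -0.69 in adipose tissue and from -2.08 to -0.22 in spleen over left-out libraries and passed in none.

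For the 138 results of genes the text may name, 2179 of 2612 values under alternatives kept their direction and side of the threshold, 381 no longer passed, 40 came to pass and 12 changed sign, none of them past the threshold. The lists these genes come from were chosen after the results were seen. Over all 298 results the naming rule can give, 59 of 5635 values changed sign, 0 of them with either value past the threshold. The interaction of Id2 (0.10) was -0.25 without WT adipose 2, -0.062 without WT spleen 3, -0.032 with quantile normalization and -0.93 without both KO libraries of experiment 2, and ranged from -0.83 to 1.04 over left-out libraries. The same ranges were -0.047 to 4.55 for Id1 in WT adipose tissue against spleen, -0.20 to 3.33 for Tcf4 and -2.03 to 0.032 for Pim2 in KO against WT adipose tissue. In KO against WT spleen they were -2.89 to 0.20 for Ccr2 and -2.46 to 0.0375 for Klrg1, and both upper values were also those without both KO libraries of experiment 2.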

Other observations

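The tests and genes given here were planned by list, but which to describe was chosen after the results were seen. Il18 was at 0.474 and 0 TPM in WT adipose tissue and 33.3 and 63.9 TPM in KO adipose tissue, and between 16.6 and 27.2 TPM in the spleen libraries. It was among the 37 genes called as higher in KO against WT adipose tissue with all 8 libraries. With the 4 adipose libraries alone limma called 0 genes. Id3 was at 25.1 and 22.3 TPM in WT adipose tissue against 322 and 276 TPM in WT spleen, opposite in direction to Id2, and did not pass over all genes by limma (-3.60, SE 0.52, adjusted p = 0.0506). It passed with a filter at 5 TPM (adjusted p = 0.0305), with library quality weights (0.00662) and with hemoglobin and mitochondrial genes left out (0.0446). The glucose transporter gene Slc2a3 was at 42.8 and 42.5 TPM in WT and 8.82 and 11.9 TPM in KO adipose tissue (adjusted p = 0.358).

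Further lists were called for adipose tissue against spleen in WT. The Th2 and Th17 lists were higher (medians 1.19 and 1.15, both adjusted p = 0.0466, and adjusted p = 0.604 with an estimated correlation). Without WT adipose 3 they had adjusted p = 0.103 and 0.124, and without any 1 library of KO or without WT spleen 2 they were not called either (0.0502 to 0.112). They had 0.134 and 0.115 without both KO libraries of experiment 2, and after quantile normalization the Th2 list had 0.0819. With the replicate block Il5 of the Th2 list passed over all genes (adjusted p = 0.049), as it did without WT adipose 2 (0.0136), with a filter at 5 TPM (0.044), with library quality weights (0.0206) and with a pseudocount of 0.1 (0.0379). The interferon response list was lower (12 of 20 negative, median -0.36, camera adjusted p = 0.00976, adjusted p = 0.737 with an estimated correlation), and was not called without WT adipose 3 (adjusted p = 0.14). CD8 T and NK cell genes (5 of 7 negative, median -1.48, camera adjusted p = 0.01, adjusted p = 0.42 with an estimated correlation) and B and plasma cell genes (7 of 9 negative, median -1.30, camera adjusted p = 0.000485, adjusted p = 0.362 with an estimated correlation) were lower. The CD8 T and NK call ended without WT adipose 3 (0.279) or WT spleen 2 (0.0541) and after quantile normalization (0.125), and that of B and plasma cells without WT spleen 2 (0.117). With a filter at 5 TPM the Th2, Th17 and CD8 T and NK calls ended (0.0834, 0.0636 and 0.0834). In KO, follicular helper genes (9 of 10 negative, median -1.08, camera adjusted p = 0.00194, adjusted p = 0.316 with an estimated correlation), T cell core genes (11 of 11 negative, median -0.41, camera adjusted p = 0.0431, adjusted p = 0.642 with an estimated correlation) and B and plasma cell genes (7 of 9 negative, median -1.68, camera adjusted p = 0.0049, adjusted p = 0.458 with an estimated correlation) were called. Without KO adipose 3 these had adjusted p = 0.123, 0.957 and 0.0955. Without KO spleen 2 the T cell core and B and plasma cell lists had 0.0847 and 0.141, and without KO spleen 3 the T cell core list had 0.0843. After quantile normalization these 2 lists had 0.179 and 0.0789, and without both KO libraries of experiment 2 the B and plasma cell list had 0.202. The TNF receptor and NF-kB, effector Treg function, Th1, pro-survival, pro-apoptotic and E and Id protein lists were called in none of the 5 contrasts with all 8 libraries. Some of them were called with fewer libraries. The TNF receptor and NF-kB list was called for KO against WT in spleen without WT spleen 2 (adjusted p = 0.0104). The Th1 list was called for KO against WT in adipose tissue without WT adipose 3 (0.000199), without KO adipose 2 (0.00315) and without both KO libraries of experiment 2 (0.00637), and for the interaction in the same fits (0.000263, 0.00281 and 0.012). Between the tissues it was called in WT without WT adipose 3 (0.00056), and in KO without KO adipose 2 (0.0334) and without both KO libraries of experiment 2 (0.0406). Without KO adipose 2 the E and Id protein list was called for KO against WT in adipose tissue (0.0401), between the tissues in KO (0.0386) and for the interaction (0.0218). Without both KO libraries of experiment 2 it was called for the latter contrasts alone (0.0108 and 0.0497).

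Libraries of a group differed in several measures. Hemoglobin transcripts took 0.00381% and 0.38% of TPM in WT adipose tissue, 3.46% and 6.55% in KO adipose tissue, 1.57% and 4.66% in WT spleen, and 0.118% and 10.7% in KO spleen. Mitochondrial transcripts took 9.28% and 8.35% in WT adipose tissue and 18.4% and 12.9% in WT spleen. The cell cycle list summed to 2085 and 1137 TPM in WT adipose tissue and to 329.8 and 785 TPM in KO adipose tissue. The Th1 list summed to 2706 TPM in WT adipose 2 and 2442 TPM in KO adipose 2, and to 435 and 177 TPM in the adipose libraries of experiment 3. Cd3e, a subunit of the T cell receptor complex, was at 70.6 TPM in KO adipose 2 and 67.3 TPM in KO spleen 2. It was at 172 and 266 TPM in the WT libraries of experiment 2, and between 393 and 847 TPM in experiment 3. The neutrophil list, with too few members above the filter for a test, summed to at most 8.57 TPM in any library. The mast cell and basophil list, also untested, summed to 147 TPM in WT adipose 3 and to 49 TPM in KO adipose 3.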
